A study of Mus musculus with 16 samples.

How the data were processed

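RNA of mouse kidneys was measured by QuantSeq, a 3' RNA sequencing method that reads the end of each transcript near its poly(A) tail. The 16 libraries fall into 4 groups of male C57BL/6 mice: Young (5 libraries, 3 months of age), Old (5 libraries, untreated), Old + YM (3 libraries) and Old + PM (3 libraries). YM is Yukmijihwang-tang and PM is Palmijihwang-tang, herbal formulas given by mouth at 100 mg/kg/day on 5 days a week from 19 to 24 months of age. One passage of the labels gives the PM dose as a dose of YM, and the group name and the rest of the design text were followed. The age of the untreated Old mice at sampling is not given in the sources used here. An acclimatization of 5 months is given for the Old, Old + YM and Old + PM mice, and no value for Young. The labels do not say that each library came from its own mouse, so the p-values below measure only the spread between these libraries.

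The deposited files hold raw counts per gene symbol, 1 value per library, whole numbers with no normalization. Per the labels, the authors aligned reads with Bowtie2 to the mm10 build of the mouse genome and counted them with bedtools. Versions, annotation, strand setting and the treatment of reads with several alignments are not given in the sources used here. The table lists 40879 gene symbols, of which 24634 had a count in any library. Totals ran from 8223008 to 10914515 counts per library. At the lowest total, 8223008 counts, 1 CPM (counts-per-million unit) is about 8 counts. Coordinates are those of the mouse build GRCm38 (mm10) in GENCODE M21, where 29035 of the symbols were found, and the deposited files themselves give none.

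Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr (minimum count 10, smallest group 3), which left 14665 genes and removed 26214. Library sizes were scaled by TMM. All 16 libraries entered 1 quasi-likelihood fit with robust dispersions and a term for group, and 4 comparisons were tested two-sided: Old against Young, Old + YM against Old, Old + PM against Old, and Old + PM against Old + YM. Benjamini-Hochberg adjustment covered all 14665 genes of a comparison, at a threshold of 0.05. Values are mean CPM on TMM-scaled library sizes ± SD, and log2 fold changes carry the standard error (SE) of the edgeR fit.

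Gene lists numbering 40 were written down in advance for kidney cell types, immune cells, neighbouring tissues (adipose, adrenal, liver, muscle, urothelium, blood) and pathways. Of these, 37 had at least 5 tested members. Neutrophil, adrenal and muscle markers had 3, 2 and 2 and were not tested as lists. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 37 lists of a comparison. Beside it stand camera with an estimated correlation, the rotation test fry, and the number of members past the threshold, once adjusted over all genes and once adjusted over the list alone. Some lists share members, such as C1qa in the complement and macrophage lists, Cdkn1a in the senescence and DNA damage lists, and Acsm3 in the male-biased and fatty acid lists.

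An age score was made per library as the mean z-scored log2 CPM (prior count 2) of genes higher in Old than in Young minus that of genes lower in Old. Each Old library was scored with genes chosen without it, and each treated library with the mean of those 5 scorings. Young libraries also got the mean of the 5, but took part in choosing and scaling the genes of each, so their scores are not held out. Treated and Old scores were compared by exact permutation of the labels, two-sided. An Old library has only its own scoring and a treated library the mean of 5, so the labels are not fully exchangeable. The treatment effect was also compared with the age effect across all tested genes by Pearson r. Because both effects use the Old libraries with opposite sign, Old was split into separate sets of 2 and 3 libraries, over all such splits, and the p-value came from permuting the labels. Simulated unchanged groups, 100 of them, stand beside these values.

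Genes named in the text follow a rule: the 8 largest rises and the 8 largest falls among genes that passed, had a mean of at least 5 CPM and did not overlap between groups. To these come up to 3 members of each list that passed, and 25 preset kidney genes. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p are given as not passing. About 30 genes per comparison were allowed, and the members of lists were narrowed to that number after their values had been printed. Genes outside the rule are said to have been chosen after their values were seen. A few genes that the rule names are not reported here. The groups, the 4 comparisons, the tests, the 40 lists, the naming rule and a set of alternatives were fixed before the data were examined.

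Alternatives chosen at that stage were DESeq2 1.42.0 size factors and upper quartile scaling in edgeR, library sizes without the 20 most abundant genes, no filter beyond 1 count, and a filter of 5 CPM in at least 3 libraries. Others were the DESeq2 Wald test, limma-voom, non-robust dispersions, a fit of only the groups compared, a block for replicate number, a fold change of at least 1.5, and leaving out each library in turn. Added after the data were seen were covariates for a technical score, a component score, the GC slope of transcript ends and a clock score, and a fit without 3 libraries. The technical score is the mean log2 CPM of 50 genes with the largest weight on the first component of differences within groups, which held 47.1% of the within-group variance. The component score is the same component found without the Old + YM libraries. Genes of the clock score were left out of the technical score. No measure of batch or RNA quality entered either score, so differences between animals may load on them too, and the word technical is only a label. The clock score is the mean log2 CPM of clock output genes minus that of Bmal1, Npas2, Clock and Nfil3. Exploratory looks at the library differences preceded these choices and were not kept.

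The gene test was checked on simulated counts in which 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. For groups of 5 against 5, it recovered 26.9%, 55.2% and 89.4% of them. For Old + YM against Old it recovered 10.4%, 52.2% and 84.8%, for Old + PM against Old 17.9%, 50.7% and 86.4%, and for Old + PM against Old + YM 10.4%, 46.3% and 77.3%. No pair of libraries within a group was a duplicate: over 26 pairs, the chi-square per degree of freedom of their counts lay between 7.71 and 68.4. Sex-linked transcripts matched the labels in all 16 libraries, with at most 4 counts of Xist and at least 456 of Ddx3y. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.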

Results

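Kidney RNA of 16 libraries was counted per gene by 3' sequencing, with 5 libraries of Young, 5 of Old, 3 of Old + YM and 3 of Old + PM mice and totals of 8223008 to 10914515 counts. The share of counts from the mitochondrial genome was 21.8% ± 4.24 (SD, n = 5) in Young, 20.3% ± 1.68 (n = 5) in Old, 20.6% ± 3.54 (n = 3) in Old + YM and 16.5% ± 1.52 (n = 3) in Old + PM. The first principal component of the 2000 most variable genes held 31.6% of the variance and the second 15.7%. All 5 Young libraries had negative values on the first component. Old 4 and Old + PM 3 were the aged libraries with negative values there.

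The comparison of Old with Young was meant to address natural ageing of the male kidney. Neither the origin of the mice nor the time of collection is given in the sources used here. Changes between Old and Young may therefore reflect these beside age. As lists, B and plasma cell genes and female-biased genes were higher and male-biased genes lower in Old kidneys, also with an estimated correlation between genes. Of other lists, 17 of 22 macrophage genes and 10 of 23 tubule injury genes rose and 25 of 75 respiratory chain genes fell, and the calls of these lists were lost with an estimated correlation (adjusted p = 0.331, adjusted p = 0.131 and adjusted p = 0.141). Igkc, the constant region of the antibody kappa light chain, was 15.4-fold higher in Old, and Havcr1, the tubule injury marker KIM-1, was 20.4-fold higher. Young libraries held only 0 to 0.755 CPM of Havcr1, so the size of its fold change is uncertain. Transcripts that fell included Kap, the androgen-dependent kidney protein, to 15952 ± 3729 CPM (n = 5) in Old from 32289 ± 3264 CPM (n = 5) in Young. Of 14665 genes tested with edgeR, 1995 (13.6%) changed, 949 higher and 1046 lower in Old. Of these, 480 rose and 138 fell by at least 2-fold, and at an unadjusted p under 0.05 there were 4120 genes against 733.25 expected by chance. Groups did not overlap for 1347 genes (9.19%, where chance gives 0.794%), among them 1140 of the changed genes. The count was 1208 without Old 5 and 1236 without Young 4. With the clock score as a covariate it was 379, but that score parts all Old libraries except Old 4 from Young. It therefore overlaps with the comparison itself and enlarges the errors. The balance depended on the scaling: with upper quartile scaling 1104 genes were higher and 758 lower.

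Immune cell markers were higher in Old. Of 16 tested B and plasma cell genes, 10 rose (15 adjusted over the list alone) and none fell, and the list passed camera (adjusted p = 2.13e-09, and adjusted p = 0.0467 with an estimated correlation). Igkc on chromosome 6 (70726435 to 70726966, plus strand) had 56.1 ± 23.3 CPM (n = 5) in Old and 3.65 ± 2.05 CPM (n = 5) in Young (log2 3.94, SE 0.45, edgeR adjusted p = 0.000207). Ighm, the heavy chain of IgM, rose by log2 5.15 (SE 0.79). Ighg2c, an IgG heavy chain, had 10.9 ± 12.2 CPM in Old, while Young 5 was the only Young library with a count. Its fitted change of log2 7.60 (adjusted p = 0.0249) depended on the prior count and is no bound, and the call was lost when any of the 5 Young libraries was left out (adjusted p from 0.0583 to 0.0877). Of 22 macrophage and dendritic cell genes 17 rose and none fell (19 higher and 1 lower adjusted over the list alone; adjusted p = 8.55e-09, and adjusted p = 0.331 with an estimated correlation). The level of that list was 6.34 in Old 5 and 3.99 to 4.69 in the other Old libraries, and without Old 5, 15 of its genes rose and 1 fell. Mrc1, a mannose receptor of tissue macrophages, rose by log2 1.76 (SE 0.40), and by 1.29 without Old 5. Of 13 T and NK cell genes 7 rose (11 adjusted over the list alone; adjusted p = 4.88e-05, and adjusted p = 0.350 with an estimated correlation). Ccl5, a chemokine of activated T cells, had 31.0 ± 51.2 CPM in Old and 1.97 ± 0.674 CPM in Young (log2 3.97, adjusted p = 0.0197). Old 5 alone held 122.5 CPM of Ccl5, and without Old 5 its log2 change was 2.04 and 2 of 10 tested T and NK genes rose. The call of Ccl5 was lost with limma-voom (adjusted p = 0.0962), in a fit of these groups only (0.0543) and with the component, GC slope or clock score, over a range of 0.0522 to 0.325. Macrophage genes that rose numbered 10 without Young 1 and 11 without Young 3 or Young 4. B and plasma genes that rose numbered 6 without Young 1 or Young 2, 5 without Young 3 and 4 without Young 4, and T and NK genes 4 without Young 1 or Young 5 and 3 without Young 2, Young 3 or Young 4.

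Complement genes rose in 12 of 16 cases (13 adjusted over the list alone; adjusted p = 2.86e-08, and adjusted p = 0.131 with an estimated correlation). C3, the central complement protein, went from 6.04 ± 2.55 CPM in Young to 40.1 ± 36.9 CPM in Old (log2 2.73, SE 0.51, adjusted p = 0.00426). Old 5 held 105.4 CPM of C3, and the other Old libraries 18.5 to 33.2 CPM. Interferon response genes rose in 3 of 26 cases (5 adjusted over the list alone; adjusted p = 0.000217, and adjusted p = 0.502 with an estimated correlation), and class I antigen presentation genes in 2 of 13 (3 adjusted over the list alone; adjusted p = 0.00390, and adjusted p = 0.502 with an estimated correlation). Ifit2, an interferon-induced gene, rose by log2 1.15, and Tap1, a peptide transporter of antigen presentation, by log2 1.74. Old 5 was the highest Old library on the complement, interferon and class I lists. Without Old 5, the log2 change was 1.97 for C3 and 0.92 for Tap1, 9 complement genes rose, no interferon gene did, and Ifit2 had an adjusted p of 0.0581. Tap1 had an adjusted p of 0.0515 without Young 3, and its call was lost with no filter, limma-voom (0.0502), a fit of these groups only (0.0561) and the component, GC slope or clock score, over a range of 0.0502 to 0.367. Without Young 1 or Young 4, 7 complement genes rose. Interferon genes that rose numbered 1 without Young 1, Young 3 or Young 4, and 5 without Old 4. No class I gene rose without Young 3, and 1 did without any other Young library or any treated library except Old + PM 3.

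Tubule injury genes rose in 10 of 23 cases and none fell (12 adjusted over the list alone; adjusted p = 9.03e-08, and adjusted p = 0.131 with an estimated correlation). Havcr1 on chromosome 11 (46735080 to 46779578, plus strand) had 6.82 ± 4.62 CPM (n = 5) in Old and 0.314 ± 0.311 CPM (n = 5) in Young (log2 4.35, SE 0.74, edgeR adjusted p = 0.00159), and the call was lost with the clock score (log2 3.62, SE 0.99, adjusted p = 0.0683) and with the clock and technical scores (adjusted p = 0.170). Lcn2, which encodes the injury marker NGAL, rose by log2 2.16 (adjusted p = 0.0172, and 0.0610 without Old 5, 0.0973 with limma-voom and 0.194 with the clock score). Genes of senescence and its secreted factors rose in 9 of 29 cases and 1, Glb1, which encodes lysosomal beta-galactosidase, fell (16 higher and 1 lower adjusted over the list alone; adjusted p = 2.40e-07, and adjusted p = 0.141 with an estimated correlation). The level of that list was 4.14 in Old 5 and 2.90 to 3.26 in the other Old libraries, and 2.67 in Young 5 and 2.05 to 2.14 in the other Young libraries, and with the clock score 2 of its genes rose. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by log2 1.09 (SE 0.19, adjusted p = 0.001004). DNA damage genes rose in 5 of 21 cases (5 adjusted over the list alone; adjusted p = 0.00288, and adjusted p = 0.224 with an estimated correlation), and in 3 without Old 5 or without Young 4. Cdkn2a was removed by the filter, with 40 counts in Old 5 and at most 4 in every other library. Extracellular matrix genes rose in 8 of 35 cases (10 adjusted over the list alone; adjusted p = 7.73e-06, and adjusted p = 0.371 with an estimated correlation). Col1a1, a chain of fibrillar collagen, rose by log2 1.07 (SE 0.34, adjusted p = 0.0449). That call was kept only without Young 5, Old 2, Old 3 or Old 4, and without any of the other 12 libraries its adjusted p lay between 0.0507 and 0.130.

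The sex-typical programs of the kidney moved in opposite directions. Of 18 male-biased genes 14 fell and 1 rose (15 lower and 1 higher adjusted over the list alone; adjusted p = 1.28e-20, and adjusted p = 0.0147 with an estimated correlation). Kap fell by 1.02 on the log2 scale (SE 0.15). Odc1, the rate-limiting enzyme of polyamine synthesis and androgen-dependent in the mouse kidney, fell by 1.87 (SE 0.17, adjusted p = 2.32e-06), to 67.4 ± 16.1 CPM from 246 ± 31.6 CPM. Log2 changes were -3.22 for Slco1a1, a transporter of organic anions and steroid conjugates, -1.89 for Cyp7b1, an oxysterol hydroxylase, and -2.41 for Acsm3, a medium-chain acyl-CoA synthetase. The last exon of Acsm3 overlaps Eri2 on the other strand, and the strand setting of the counts is not given. The single male-biased gene that rose was Cyp4a12b, a fatty acid hydroxylase (log2 1.47, SE 0.23, adjusted p = 0.000630), which was chosen after its values were seen. Of 10 female-biased genes 6 rose (6 higher and 1 lower adjusted over the list alone; adjusted p = 5.32e-10, and adjusted p = 0.00550 with an estimated correlation). Cyp4a14, a fatty acid hydroxylase on chromosome 4 (115486200 to 115496142, minus strand), had 231 ± 158 CPM in Old and 12.7 ± 5.34 CPM in Young (log2 4.18, SE 0.52, adjusted p = 0.000418). Kynu, an enzyme of tryptophan breakdown, rose by log2 3.24. Old 5 was the lowest Old library on the male-biased and the highest on the female-biased list, and without Old 5, 12 male-biased genes fell and 5 female-biased genes rose.

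Genes of the nuclear-encoded respiratory chain fell in 25 of 75 cases and none rose (36 adjusted over the list alone; adjusted p = 1.31e-10, and adjusted p = 0.141 with an estimated correlation). Ndufa10, a subunit of complex I, fell by 0.52 on the log2 scale (SE 0.09). Of the 75, 11 fell without Young 1, 14 without Young 2, 13 without Young 3, 12 without Young 4, 16 without Old 1, 15 without Old 5 and 45 with the technical score as a covariate. Genes of cytosolic ribosomal proteins rose in 17 of 68 cases (22 adjusted over the list alone; adjusted p = 1.90e-07, and adjusted p = 0.141 with an estimated correlation), for example Rps4x by log2 0.57 (SE 0.11). Of the 68, 9 rose without Young 2 or Old 5, 10 without Young 3, Young 4 or Old 3, 11 without Young 1 or Old 2 and 36 with the technical score. That score holds Cox7c, Ndufa1 and Atp5j of the respiratory chain list and Rpl15, Rps23 and Rpl35a of the ribosomal list. ND3, a mitochondrially encoded subunit of complex I (M, 9459 to 9806, plus strand), rose to 10.04 ± 5.84 CPM from 0.890 ± 1.23 CPM (log2 3.60, SE 0.81, adjusted p = 0.0121, and log2 4.77 without Young 5 and 2.13, SE 1.11, adjusted p = 0.338, with the clock score). Its list was not past the threshold (adjusted p = 0.259), with 1 member higher and 1 lower of 8 (1 higher and 2 lower adjusted over the list alone), a negative median of log2 -0.29 and a positive mean of 0.14. Chaperone and unfolded protein genes fell in 11 of 28 cases and 1 rose (12 lower and 3 higher adjusted over the list alone; adjusted p = 0.000172, and adjusted p = 0.141 with an estimated correlation). Hsp90aa1, a cytosolic chaperone, fell by 0.96 (SE 0.14), and with the clock score its log2 change was -0.54 (SE 0.18, adjusted p = 0.118) and 2 genes of the list fell. Old 4 was the highest Old library for Hsp90aa1.

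Clock genes differed between the ages: 11 of 20 were higher and 3 lower in Old (14 and 5 adjusted over the list alone; adjusted p = 0.000980, and adjusted p = 0.233 with an estimated correlation). Nr1d2, a repressor of the clock loop, rose by log2 1.05 (SE 0.19). Clock scores of Young libraries ran from -3.22 to -1.55, and those of aged libraries from 1.13 to 2.83 except Old 4 (-1.90), Old + PM 3 (-0.31) and Old + YM 3 (-0.93). Of the 17 immediate early genes, which respond to stimuli and to handling, 4 rose (6 adjusted over the list alone; adjusted p = 0.00209, and adjusted p = 0.233 with an estimated correlation), among them Klf2 by log2 0.76, and 7 rose without Old 4. With the clock score as a covariate, no clock gene, no macrophage gene and no respiratory chain gene passed, 1 complement gene, 2 injured tubule genes, 3 B and plasma genes and 3 female-biased genes rose, and 10 male-biased genes fell. For most of these lists the errors grew and the changes were of similar size: macrophage genes had a median log2 change of 1.63 (median SE 0.76) with the score and 1.64 (0.47) without it, and respiratory chain genes -0.24 (0.16) and -0.26 (0.11). C3 had log2 2.63 (SE 0.79, adjusted p = 0.105) and Mrc1 1.84 (SE 0.59, adjusted p = 0.0924) with the score. Of the other genes named for this comparison in this part, Ighm, Ccl5, Ifit2, Tap1, Havcr1, Lcn2, Col1a1, Hsp90aa1, Ndufa10, Rps4x, ND3, Klf2, Nr1d2, Slc22a6 and Slc22a7 also lost their call with the score (adjusted p from 0.0518 to 0.567), and Ighg2c (0.0725), Mfsd2a (0.0987) and Ren1 (0.0912) with the clock and technical scores together. For immediate early genes the median change was 0.07 with it and 0.51 without it. Of the 20 clock genes 14 are in the score itself, which removes their change by construction. Of the other 6, 3 passed without the score and none with it, and their median absolute log2 change was 0.81 and 0.33.

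Several of the largest changes stood outside these groups. Ttr, which encodes the thyroxine carrier transthyretin, fell by 2.99 on the log2 scale (SE 0.19, adjusted p = 3.30e-08), to 60.4 ± 20.4 CPM from 479 ± 42.1 CPM. Wdfy1, an endosomal adaptor, had 11.9 ± 2.95 CPM in Old and 55.1 ± 7.08 CPM in Young (log2 -2.21, SE 0.15), and stayed at 13.4 ± 0.773 and 11.2 ± 0.827 CPM in the treated groups. Slc22a7, an organic anion transporter, fell by 3.32 and Mfsd2a, a transporter of lysophospholipids, fell by 2.81. Of 25 preset kidney genes 23 were tested and 9 passed, 6 higher and 3 lower, and 14 did not. Those that passed included Ren1, which encodes renin, down by log2 -1.32 (SE 0.17, adjusted p = 0.000117), and Slc22a6, the organic anion transporter OAT1 of the proximal tubule, down by -0.67 (SE 0.15, adjusted p = 0.00628), with Old 5 the lowest Old library.

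Further lists passed camera as well. Proximal tubule genes went both ways, 4 higher and 6 lower of 30 (4 and 8 adjusted over the list alone; Down, adjusted p = 0.00627, and adjusted p = 0.502 with an estimated correlation), and the list did not pass without Young 5 (0.0962) or Old 4 (0.05005). Its genes that rose numbered 2 without Young 1, Young 2 or Old 3 and 1 without Young 3. Of 11 collecting duct genes 1 rose and 2 fell (1 and 5 adjusted over the list alone; Down, adjusted p = 0.00390, and adjusted p = 0.0873 with an estimated correlation), and 4 fell without Young 5, Old 2 or Old 4. Podocyte genes rose in 3 of 12 cases (3 adjusted over the list alone; adjusted p = 0.0249, adjusted p = 0.131 with an estimated correlation, and adjusted p = 0.0522 without Young 3), and in 1 without Young 3 or Old 2. Cholesterol synthesis genes fell in 4 of 20 cases and rose in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0308, and adjusted p = 0.502 with an estimated correlation). That list did not pass without Young 1, Young 3, Old 1, Old 3 or Old 5 (adjusted p from 0.0525 to 0.0833), and 2 of its genes fell without Young 1 or Young 4 and 8 without Old 4. Its median log2 change was -0.26, and 0.21 with the clock score. Adipose genes fell in 2 of 12 cases (3 adjusted over the list alone; adjusted p = 0.00630, and adjusted p = 0.457 with an estimated correlation), and in 1 without Young 2, Young 4, Young 5, Old 4 or Old 5, and the list level varied between Young libraries from 0.35 to 3.20 on the log2 scale. In all, 22 of 37 lists passed camera, 15 up and 7 down. With an estimated correlation 3 did, the male-biased, the female-biased and the B and plasma lists, and fry, which asks whether the genes of a list move on balance one way, gave 17. Fry's mixed test, which counts changes in either direction, gave 30.

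**Figure D1:**
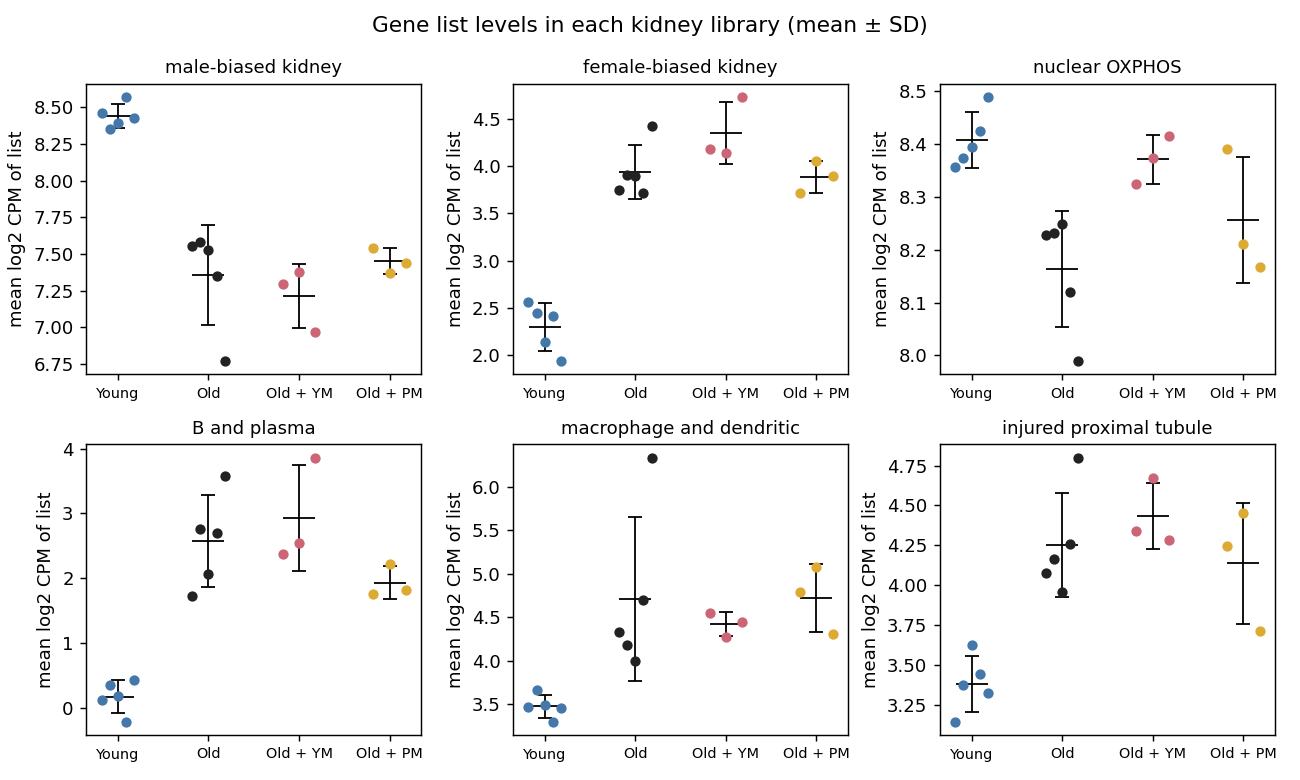
Mean log2 CPM of 6 gene lists in each of the 16 libraries (points), by group, with the group mean and SD as lines. Male-biased genes lay at 8.44 ± 0.08 in Young, 7.36 ± 0.34 in Old, 7.21 ± 0.22 in Old + YM and 7.45 ± 0.09 in Old + PM, and B and plasma genes at 0.17 ± 0.25, 2.57 ± 0.71, 2.92 ± 0.82 and 1.93 ± 0.25.

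**Figure D2:**
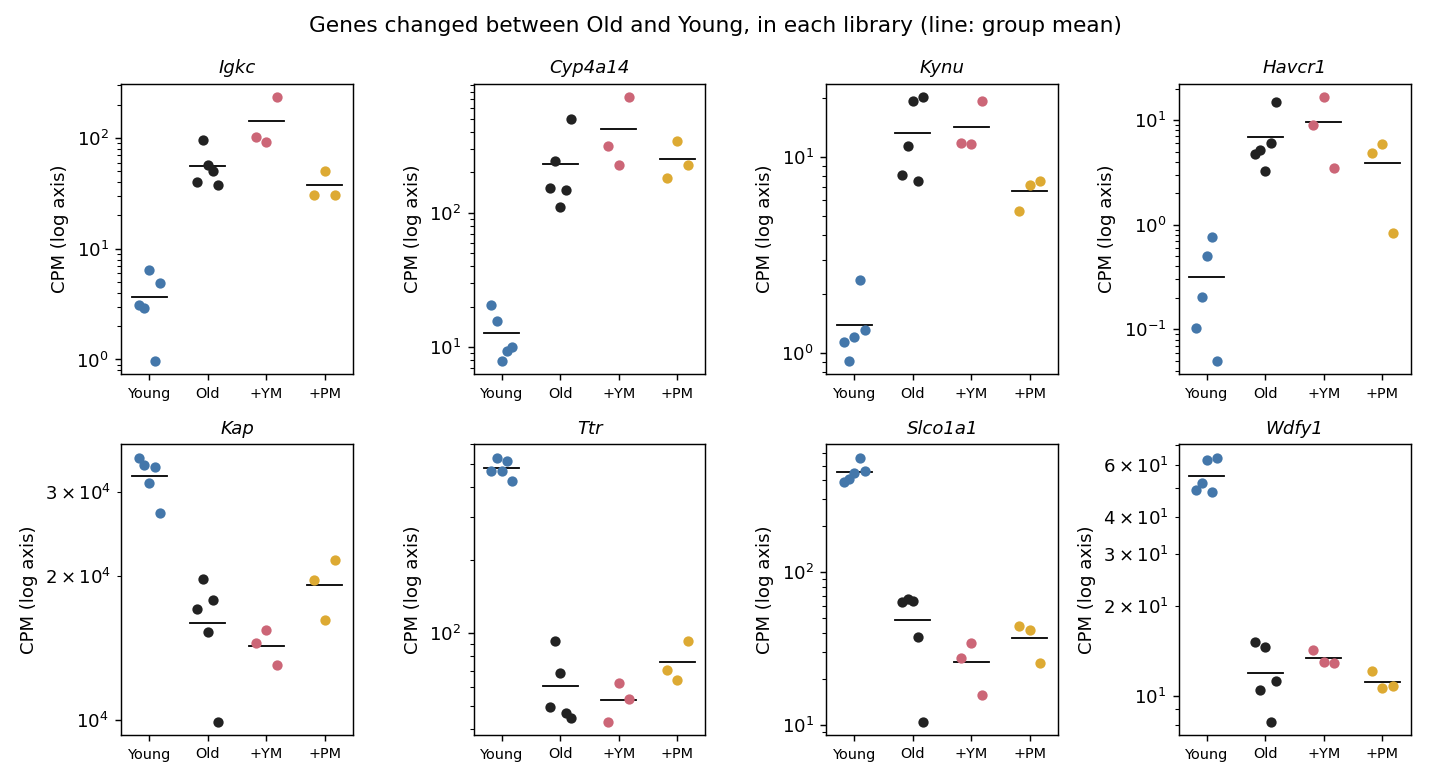
CPM on a log axis of 8 genes that changed between Old and Young, in each library (points) with group means as lines and values under 0.05 CPM drawn at 0.05. The Old mean of Kynu was 13.2 CPM against 1.39 in Young, and the Old mean of Slco1a1 was 48.5 CPM against 453 in Young.

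Old + YM was compared with Old to ask what Yukmijihwang-tang changed in the aged kidney. With edgeR 3 genes passed, all of them higher with YM and none lower, while DESeq2 gave 49, 34 higher and 15 lower, and a fit of these groups only gave 20, 18 higher and 2 lower. Usp19, a ubiquitin-specific protease, had 66.5 ± 4.63 CPM (n = 3) with YM and 31.4 ± 3.44 CPM (n = 5) in Old. Rps6, a ribosomal protein, had 36.8 ± 2.92 and 17.4 ± 2.83 CPM, and Arhgef10l, a guanine nucleotide exchange factor, had 30.6 ± 5.89 and 12.3 ± 1.45 CPM. For each of the 3 genes, the lowest YM library lay above the highest Old library.

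The log2 changes were 1.08 (SE 0.16, adjusted p = 0.0245) for Usp19 on chromosome 9 (108490602 to 108502337, plus strand), 1.08 (SE 0.18, adjusted p = 0.0339) for Rps6 on chromosome 4 (86854660 to 86857412, minus strand) and 1.31 (SE 0.22, adjusted p = 0.0339) for Arhgef10l on chromosome 4 (140514485 to 140666012, minus strand). Untreated Young 5 also had a high level of Usp19 (62.4 CPM) and of Arhgef10l (42.3 CPM). At an unadjusted p under 0.05 there were 1390 genes, 672 higher and 718 lower, against 733.25 expected by chance, and 9.10% of genes did not overlap, where chance gives 3.57%. Genes that did not pass included Pank4, a pantothenate kinase family member (log2 2.06, adjusted p = 0.0992), and Uap1l1, related to a UDP-sugar pyrophosphorylase (log2 -0.77, adjusted p = 0.0992). ND3, chosen after its values were seen, also did not pass: it had 147.8 ± 21.5 CPM with YM and 10.04 ± 5.84 CPM in Old (log2 3.88, SE 0.63, adjusted p = 0.0992). None of the 23 preset genes passed, as for Igkc (log2 1.35, adjusted p = 0.324), Kl, the klotho gene (0.55, 0.424), Lcn2 (1.24, 0.495) and Egf (0.44, 0.550).

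Adipose genes were the list that stood out most with YM (Up, adjusted p = 8.06e-07, and adjusted p = 0.589 with an estimated correlation). None of its 12 members passed over all genes and 2 rose adjusted over the list alone. Its level was 2.46 ± 0.70 (n = 3) with YM, 0.87 ± 0.61 (n = 5) in Old and 1.97 ± 1.15 (n = 5) in Young. Nuclear respiratory chain genes also passed as a list (Up, adjusted p = 0.00694, and adjusted p = 0.730 with an estimated correlation), with a median of log2 0.05, no member past the threshold of 75 and none adjusted over the list alone. The mean level of that list was 8.37 ± 0.05 (n = 3) with YM and 8.16 ± 0.11 (n = 5) in Old. That list was lost without Old 5 (0.318) or Old + YM 3 (0.0644). Ribosomal protein genes passed (Up, adjusted p = 0.0183, and adjusted p = 0.730 with an estimated correlation) with Rps6 alone of 68 past the threshold (1 adjusted over the list alone), and were lost without Old 1 (0.101) or Old + YM 3 (0.183). The technical score, high in all YM libraries, holds Cox7c, Ndufa1 and Atp5j of the respiratory chain list. It also holds Rpl15, Rps23 and Rpl35a of the ribosomal list. Macrophage genes had lower values (Down, adjusted p = 0.0393, and adjusted p = 0.757 with an estimated correlation), with none of 22 past the threshold and none adjusted over the list alone. They were lost without Old 5 (0.416), Old + YM 2 (0.159), Old + YM 3 (0.0510) or Old + PM 1 (0.05003). Proliferation genes were lower too (Down, adjusted p = 0.0215, and adjusted p = 0.730 with an estimated correlation; none of 21 past the threshold, none adjusted over the list alone), and lost without Old 5 (0.448) or Old + YM 2 (0.0691).

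Collecting duct genes passed as a list (Up, adjusted p = 0.0345, and adjusted p = 0.589 with an estimated correlation; none of 11 past the threshold and 2 adjusted over the list alone), but not without Old 1 (0.0889), Old 5 (0.0657) or Old + YM 2 (0.315). Immediate early genes passed (Up, adjusted p = 0.0345, and adjusted p = 0.730 with an estimated correlation; none of 17 past the threshold and 1 adjusted over the list alone) and held in 7 of the 16 fits that left out 1 library, the others giving an adjusted p of 0.0504 to 0.186. Liver genes passed (Up, adjusted p = 0.0345, and adjusted p = 0.730 with an estimated correlation; none of 11 past the threshold and none adjusted over the list alone) and held in 10 of 16, the others giving 0.0604 to 0.220. In all 8 of 37 lists passed camera, 6 up and 2 down, and none with an estimated correlation, with fry or with its mixed test.

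The calls for YM were lost in many fits without 1 library, while the log2 changes over all 16 such fits stayed at 1.04 to 1.15 for Usp19, 1.03 to 1.16 for Rps6 and 1.16 to 1.45 for Arhgef10l. Without any 1 of Old + YM 1, 2 or 3, Old 1, 2, 3 or 4, or Young 3 the count was 0, without Young 2 or Old 5 it was 1, and without Young 5 it was 39. All 3 YM libraries had technical scores of 0.94 to 1.02, above the highest Old score of 0.56, and Young 5 had 1.002. Without Old 4, Old + YM 3 and Old + PM 3 together, none of the 3 genes passed (adjusted p from 0.0675 to 0.194), at log2 1.07 for Usp19, 0.95 for Rps6 and 1.41 for Arhgef10l. The 1390 genes at an unadjusted p under 0.05 became 2234 with the clock score, 764 with the clock and technical scores and 863 without those 3 libraries. They became 1146 with the technical score alone, 1173 with the GC slope and 1180 with the component score, where 733.25 are expected by chance.

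Old + PM was compared with Old to ask the same of Palmijihwang-tang. No gene passed with edgeR, DESeq2 or limma-voom (0 each), while 904 genes had an unadjusted p under 0.05, 388 higher and 516 lower, against 733.25 expected by chance. In a fit of these groups only the count was 589, and with the replicate block 713. It was 1235 with the technical score, 1222 with the component score and 1321 with the GC slope. With the clock score it was 909, and with the clock and technical scores 1210. Without Old 4, Old + YM 3 and Old + PM 3 it was 857. The smallest adjusted p was 0.790. Ren1, the renin gene, was at 57.8 ± 3.67 CPM (n = 3) with PM and 35.2 ± 9.80 CPM (n = 5) in Old, without overlap (log2 0.72, SE 0.20, adjusted p = 0.790). Slc25a1, the mitochondrial citrate carrier, was at 97.5 ± 6.25 and 71.7 ± 5.54 CPM (log2 0.44, SE 0.10, adjusted p = 0.790).

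The other genes with the smallest unadjusted p, none of which passed, were Swap70, a regulator of B cell signalling (log2 -0.96), Tulp4 (-0.94), Gm15348 (1.42) and 3300005D01Rik (-2.42), each at an adjusted p of 0.790. None of the 23 preset genes passed, as for Umod, which encodes uromodulin (log2 0.25), Tgfb1 (0.51), Lrp2, the megalin gene (-0.30), and Kap (0.26), with adjusted p from 0.790 to 0.850 in these and Ren1. Groups did not overlap for 4.02% of genes, where chance gives 3.57%.

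Respiratory chain genes had the smallest camera p of the PM lists (Up, adjusted p = 3.15e-07, and adjusted p = 0.905 with an estimated correlation), with a median of log2 0.12, none of 75 members past the threshold and none adjusted over the list alone. The shift was small, with a list level of 8.26 ± 0.12 (n = 3) with PM and 8.16 ± 0.11 (n = 5) in Old. Proliferation genes were lower (Down, adjusted p = 0.00554, and adjusted p = 0.905 with an estimated correlation; none of 21 past the threshold, none adjusted over the list alone), and lost without Old 5 (0.405). Liver genes were higher (Up, adjusted p = 0.0111, and adjusted p = 0.905 with an estimated correlation; none of 11 past the threshold and 1 adjusted over the list alone), and lost without Old 1 (0.141), Old 4 (0.192), Old + PM 1 (0.0616) or Old + PM 2 (0.421). B and plasma genes were lower (Down, adjusted p = 0.0311, and adjusted p = 0.905 with an estimated correlation; none of 16 past the threshold, none adjusted over the list alone), and lost without Old 2 (0.0776), Old 4 (0.107), Old 5 (0.0840) or Old + PM 1 (0.311). Mitochondrially encoded genes were lower (Down, adjusted p = 0.0311, and adjusted p = 0.905 with an estimated correlation; none of 8 past the threshold, none adjusted over the list alone), and lost without Old 2 (0.0842), Old 3 (0.0702), Old 4 (0.156) or Old + PM 2 (0.341). Blood genes were lower (Down, adjusted p = 0.0321, and adjusted p = 0.905 with an estimated correlation; none of 8 past the threshold, none adjusted over the list alone), and lost without Old 1 (0.141), Old 3 (0.133), Old 4 (0.0774), Old + PM 1 (0.130) or Old + PM 2 (0.319). These were 6 of 37 lists, 2 up and 4 down. None passed with an estimated correlation or fry. In fry's mixed test, which counts changes in either direction, the renin-angiotensin list passed (adjusted p = 0.00814), with none of 17 members past the threshold and 2 higher adjusted over the list alone.

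Old + PM and Old + YM were compared directly, as both formulas were given at the same dose and schedule. With edgeR 0 genes passed, while 1878 had an unadjusted p under 0.05, 888 higher and 990 lower with PM, against 733.25 expected by chance. DESeq2 gave 58 genes and limma-voom 2. Technical scores were 0.97 ± 0.04 (n = 3) with YM and -0.45 ± 1.14 (n = 3) with PM, and the 1878 became 798 with the technical score as a covariate, 886 with the component score, 703 with the GC slope, 625 with the clock and technical scores and 1013 without Old 4, Old + YM 3 and Old + PM 3, and 2336 with the clock score, 2252 in a fit of these groups only and 2097 with the replicate block. Usp19 was at 30.8 ± 3.54 CPM (n = 3) with PM and 66.5 ± 4.63 CPM (n = 3) with YM (log2 -1.11, SE 0.19, adjusted p = 0.0594). Igkc was at 37.4 ± 11.6 and 143 ± 80.2 CPM (log2 -1.94, SE 0.49, adjusted p = 0.258).

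Spred2, an inhibitor of Ras signalling, stood at log2 -1.35 (adjusted p = 0.0594), and Armc8 (-1.16, 0.108), Selenoi, a selenoprotein of phospholipid synthesis (-1.61, 0.125), and Rps6 (-1.06, 0.145) followed. Preset genes did not pass either, as for Kl (log2 -0.70, adjusted p = 0.285), Ren1 (0.72, 0.261) and Tgfb1 (0.91, 0.311). ND3, chosen after its values were seen, was at 11.9 ± 10.7 CPM with PM and 147.8 ± 21.5 CPM with YM (log2 -3.63, SE 0.76, adjusted p = 0.226). Groups did not overlap for 23.8% of genes, where chance gives 10%. Without Young 5, which belongs to neither group but shapes the shared spread, 32 genes passed.

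The 5 lists past camera were all lower with PM, none with an estimated correlation or fry. In fry's mixed test 1 of the 37 lists passed. Adipose genes had an adjusted p of 0.00642 (adjusted p = 0.830 with an estimated correlation; none of 12 past the threshold, none adjusted over the list alone), and 0.0636 without Old + PM 2. B and plasma genes had 0.0377 (adjusted p = 0.830 with an estimated correlation; none of 16 past the threshold, 2 lower adjusted over the list alone) and held in 9 of the 16 fits that left out 1 library, the others giving 0.0507 to 0.375. Mitochondrially encoded genes had 0.0377 (adjusted p = 0.891 with an estimated correlation; none of 8 past the threshold, 3 lower adjusted over the list alone), and were lost without Old + YM 2 (0.236) or Old + PM 2 (0.212). Immediate early genes had 0.0377 (adjusted p = 0.830 with an estimated correlation; none of 17 past the threshold, none adjusted over the list alone) and held in 11 of 16, the others giving 0.0636 to 0.277. Ribosomal protein genes had 0.0377 (adjusted p = 0.996 with an estimated correlation; none of 68 past the threshold, 3 lower adjusted over the list alone), and were lost without Old + YM 3 (0.367) or Old + PM 3 (0.147). Rpl15, Rps23 and Rpl35a of that list are in the technical score.

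The age score asked whether treated kidneys lay nearer to Young than untreated Old kidneys did. Scores were -1.40 ± 0.25 (SD, n = 5) in Young, 1.38 ± 1.15 (n = 5) in Old, 1.62 ± 0.18 (n = 3) with YM and 1.19 ± 0.47 (n = 3) with PM. Young libraries helped to choose the genes, so their mean and SD are not comparable with those of the other groups. The YM score was 0.238 above Old (exact permutation p = 0.679, two-sided) and the PM score differed by -0.197 (exact permutation p = 0.821), over 56 splits with a smallest possible p of 0.0179. With the technical score regressed out the YM difference was -0.210 and with the clock score -0.280, and with 1 library left out it was 0.0345 (without Old 4) to 0.629 (without Old 5). Without Old 5 the PM difference was 0.207 and without Old + PM 3 it was 0.0941. Each Old library was scored with 1207 to 2655 genes.

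Across the 14665 genes, the YM effect and the age effect had a Pearson r of 0.0645 with Old split into separate sets (permutation p = 0.643), and the PM effect and the age effect an r of -0.0405 (permutation p = 0.929). Over the 1995 genes called for age, r was -0.0161 for YM (permutation p = 0.982) and -0.285 for PM (permutation p = 0.5). These genes were chosen with all Old libraries, and the split does not undo that choice. The choice pushes r to the negative side by itself, so these values do not speak for a reversal of ageing. Genes are not independent replicates, and a reversal of ageing would give a negative r. Without the split, where both effects share the Old libraries, r was -0.117 for YM and -0.314 for PM, and simulated groups with no treatment effect gave -0.204 and -0.206. The effects of the 2 formulas against Old had a split r of -0.124 (permutation p = 0.255, 9240 permutations) and an unsplit r of 0.157, where simulated unchanged groups gave 0.374. Observed split values lay outside the range of the 100 simulations, in which genes varied independently, but inside that of permuted labels. At an unadjusted p under 0.05, 33 genes were higher with both formulas and 103 lower, where 17.8 and 25.3 would be shared if the formulas were independent, and sharing the Old libraries raises such overlap by itself.

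**Figure D3:**
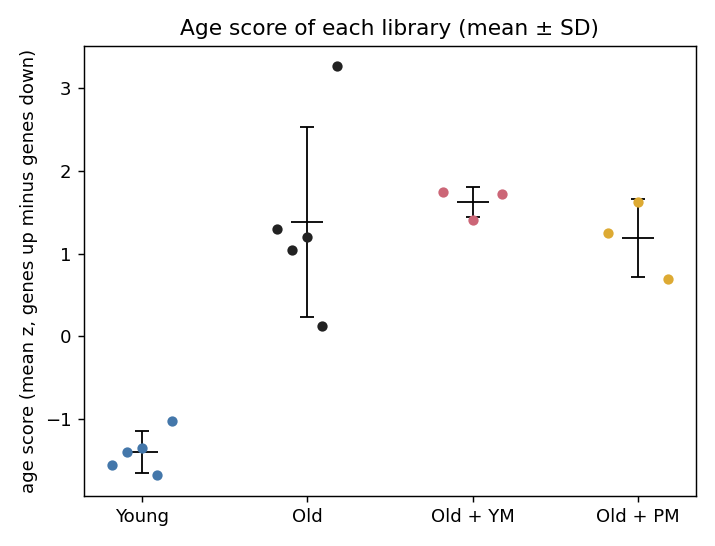
Age score of each library (points) by group, with group mean and SD as lines, in units of mean z-score. Young libraries lie between -1.68 and -1.02, Old libraries between 0.128 and 3.26, YM libraries between 1.41 and 1.74 and PM libraries between 0.694 and 1.62.

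**Figure D4:**
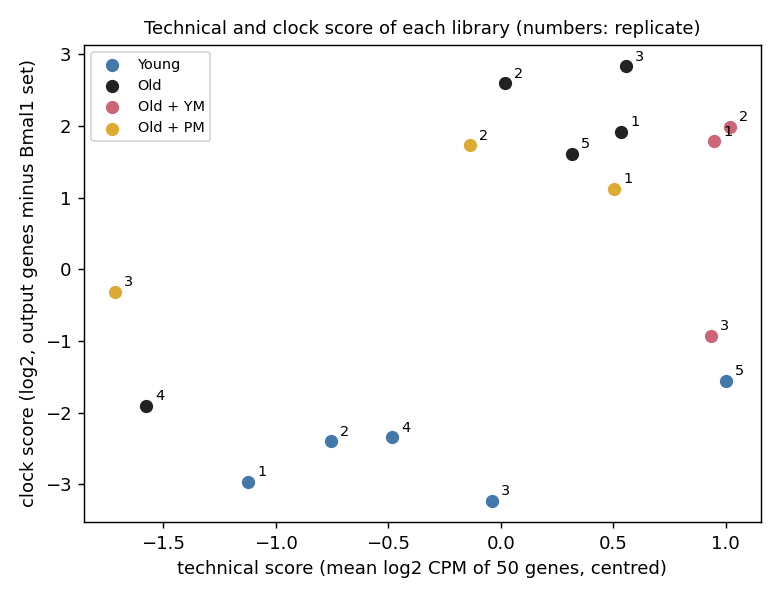
Technical score on the horizontal axis and clock score on the vertical axis, both on the log2 scale, for each of the 16 libraries, coloured by group and numbered by replicate. The 3 YM libraries lie between 0.94 and 1.02 on the technical score, and Old 4 (-1.58) and Old + PM 3 (-1.72) at its low end.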

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

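Every weighing test in this part was chosen, or reworded, after the result it measures was seen, except the one on library depth.

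Of 160 groups of 5 libraries tested, 24 held a library far from the others, where chance gives about 1 in 20 groups, or 8. The value given for each is the gap to the nearest other library as a share of the whole range of the group. Old 5 accounted for 11, Young 5 for 7, Old 4 for 4, and Young 1 and Young 4 for 1 each. The measures share genes and libraries, so these counts are not independent.

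Old 5 lay far above the other Old libraries in the levels of T and NK genes (0.8003), complement (0.726), class I antigen presentation (0.725), interferon response (0.765), senescence (0.711), female-biased (0.733) and proliferation genes (0.811), and in Ccl5 (0.826) and Tap1 (0.820). It lay far below them in male-biased genes (0.713) and Slc22a6 (0.790). Old 4 lay far below the other Old libraries in the technical score (0.748), the clock score (0.743) and the level of clock genes (0.774), and above them in Hsp90aa1 (0.762). Young 5 had the lowest total of its group (0.723) and the lowest Hsp90aa1 (0.744), and lay above the other Young libraries in senescence genes (0.865), Arhgef10l (0.909), Kl (0.759) and Usp19 (0.790). For Ighg2c it was the only Young library with a count, which makes the share 1. Young 1 was low in immediate early genes (0.850) and Young 4 in Col1a1 (0.801). Causes of these single libraries were not tested.

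The first pattern weighed is the set of genes higher with YM than in Old. Across 6725 genes, which are not independent replicates, the YM difference followed the first component of differences within the other 3 groups (Pearson r 0.677, Spearman rho 0.595), a component found without the YM libraries, and over the 6485 of these genes with a GC value it fell as the GC content of transcript ends rose (Spearman rho -0.234). Library depth stays open: after every library was thinned to the smallest total r was 0.675, but totals differ by at most 1.33 times, so that thinning could hardly move it, and the YM libraries and Young 5 have the lowest totals (8223008 to 8995881 counts). With the component score in the model the median difference of 672 genes kept 0.713 of its size. Because YM scores lay beyond the range of Old scores, treatment and a gradient between libraries, technical or not, cannot be told apart for this set. For Usp19, Rps6 and Arhgef10l the lowest ratio with and without a score was 0.781, all 3 passed with the component score and 2 with the technical score (Arhgef10l log2 1.24, SE 0.24, adjusted p = 0.0683, against 1.31, SE 0.22, without it, a smaller change with a larger error), so that a technical share in these may remain.

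The second pattern is the difference in clock genes between Old and Young. A uniform shift with age is argued against by 2 of 11 aged libraries whose clock scores lay nearer the Young mean. A gradient along the technical score, as the source of the difference between the group means, is argued against by the 15 clock genes that passed with that score in the model, against 14 without it. That score was -0.28 ± 0.82 (n = 5) in Young and -0.03 ± 0.89 (n = 5) in Old. The test does not cover differences within the aged groups, where Old 4 (-1.58) and Old + PM 3 (-1.72) had low technical scores. Old + YM 3 (0.94) did not. Over the 11 aged libraries, each against its group mean, Bmal1, Npas2, Clock and Nfil3 moved against the clock output genes (Pearson r -0.940, permutation p = 7e-05, Spearman rho -0.9, permutation p = 0.00044, two-sided), and r was -0.767 without the 2 libraries farthest from the median. Those 2 were Old 4 and Old + YM 3, so Old + PM 3, the other aged library with a low clock score, stayed in. Both permutation p-values are approximate, as deviations from a group mean are not independent and were permuted across groups. No r was computed without Old 4, Old + YM 3 and Old + PM 3 together. Another clock phase at collection may therefore contribute, and the time of collection is not given in the sources used here. An age effect on the clock itself stays open and untested.

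The third pattern is Nnt, the mitochondrial transhydrogenase gene, and Wdfy1, both lower in all aged groups; Nnt was chosen after its values were seen. Nnt had 110.9 ± 11.8 CPM in Young, 46.6 ± 3.92 in Old, 49.2 ± 4.28 with YM and 49.2 ± 1.02 with PM (log2 -1.25, SE 0.10, adjusted p = 9.12e-08 for Old against Young). GENCODE M21 holds more than 1 overlapping gene model named Nnt and the annotation behind the counts is not given, so which of its transcripts these values cover is not known. With the technical score in the model the lower of the 2 ratios of fold change was 0.994, and of the 3 aged libraries with the lowest clock scores 0 lay nearer the Young mean for both genes, which argues against a gradient along the technical score and against clock phase. Both genes are known to differ between C57BL/6 substrains, and 11 of 11 aged libraries lay below every Young library for both, so a substrain or colony difference and age cannot be told apart: all young mice differ from all aged mice in age, and their sources are not given in the sources used here. The labels also give an acclimatization of 5 months for all aged mice and no value for Young.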

How the results depend on the processing

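Tests with the technical, component, GC slope and clock scores, and the fit without Old 4, Old + YM 3 and Old + PM 3, were chosen only after the data were seen.

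The count of 1995 genes for Old against Young stayed within 1.5 times under 3 other scalings, both other filters, DESeq2 (2473), limma-voom (1824), non-robust dispersions, a fit of these groups only (1387), the technical, component and GC slope scores, and the fit without 3 libraries. With upper quartile scaling 1104 were higher and 758 lower, where TMM gave 949 and 1046. It was 1165 at a fold change of at least 1.5, which is stricter by construction. With the clock score it was 379, of which 256 were among the 1995, and with the clock and technical scores together 314. The clock score parts all Old libraries except Old 4 from Young, so it overlaps with the comparison itself. Leaving out 1 library at a time gave 1208 (without Old 5) to 2655 (without Old 4). Of 1566 values of 49 named genes, 1441 kept their direction and side of the threshold, 121 no longer passed (34 genes) and 4 reversed: Per2 to -0.88 with the clock score and -0.85 with the clock and technical scores, and with both scores Bmal1 to 0.68 and Npas2 to 0.17. These 3 genes belong to the clock score by construction.

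The 3 genes of Old + YM against Old became 6 with no filter, 49 with DESeq2, 5 with limma-voom, 20 in a fit of these groups only, 6 with the technical score, 30 with the GC slope, 24 with the clock score, 1 with clock and technical scores, 25 with the component score and 1 without the 3 libraries, which was none of the 3. Leaving out 1 library gave 0 to 39 (39 without Young 5), and the cause was not tested. ND3, which did not pass, passed with DESeq2, limma-voom, non-robust dispersions, a fit of these groups only, each single score and without Young 5 (adjusted p = 0.0221). Of 319 values of 10 named genes, 261 were the same, 36 no longer passed (3 genes), 22 came to pass (3 genes) and 0 reversed.

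Old + PM against Old gave 0 genes with edgeR (904 at an unadjusted p under 0.05), DESeq2, limma-voom and every other alternative run, 33 in all, and all 319 values of its 10 named genes were the same. Old + PM against Old + YM gave 8 with no filter, 58 with DESeq2, 2 with limma-voom, 13 in a fit of these groups only, 3 with the clock score, 1 without the 3 libraries, and 0 to 32 when 1 library was left out (32 without Young 5). The cause was not tested. Its 1878 genes at an unadjusted p under 0.05 became 798 with the technical score, 703 with the GC slope and 625 with clock and technical scores, where 733.25 are expected by chance. Of 320 values of 10 named genes, 296 were the same and 24 came to pass (6 genes).

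Replicate numbers showed no pairing: 3 of 16 libraries had their best match under the same number, and 20 pairs with the same number had a median r of 0.00243. With a block for replicate number Old + YM against Old gave 6 genes and Old + PM against Old + YM gave 1.

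Gene lists past the threshold for Old against Young numbered 22, 3 with an estimated correlation and 20 to 24 when 1 library was left out. With the clock score 19 passed, 16 of them among the 22. For Old + YM against Old the 8 lists became 0 with an estimated correlation, 0 with fry and 18 with the technical score, 6 of them among the 8. With the replicate block 7 passed, 3 of them among the 8, and without the 3 libraries 10, 5 of them among the 8. Leaving out 1 library gave 4 (without Old 1 or Old + YM 2), 5 (without Old + YM 3) and up to 12 (without Old 2 or Old + YM 1). For Old + PM against Old the 6 became 0 with an estimated correlation and 0 with fry, 3 with the filter of 5 CPM, 3 with the technical score and 13 without the 3 libraries (5 of them among the 6). Leaving out 1 library gave a range of 3 (without Old 4 or Old + PM 1) to 10 (without Old + PM 3). For Old + PM against Old + YM the 5 became 0 with an estimated correlation and 0 with fry, 3 with the filter of 5 CPM, 18 with the technical score (4 of them among the 5) and 3 with the clock score. Leaving out 1 library gave a range of 1 (without Old + PM 2) over 3 (without Young 5, Old + YM 3 or Old + PM 1) and 8 (without Old 5) to 10 (without Old + PM 3). The cause was not tested.

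The age score difference of YM was -0.210 with the technical score regressed out and -0.280 with the clock score, and 0.0345 to 0.629 when 1 library was left out (exact permutation p from 0.114 to 1). That of PM ran from -0.627 to 0.207 and reversed without Old 5 (0.207) and without Old + PM 3 (0.0941). The split r of YM with age was -0.0161 over the genes called for age and ran from 0.0162 to 0.143 with 1 library left out. That of PM was -0.285 over the genes called for age (permutation p = 0.5). Those genes were chosen with all Old libraries, which pushes r over them to the negative side. With 1 library left out the split r of PM ran from -0.160 to 0.0780 and reversed without Old 5 (0.0780) and Old + PM 3 (0.0577). The split r between the formulas ran from -0.211 to 0.0290 and reversed without Old + PM 3 (0.0290). The cause was not tested.

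Many small changes would be missed: on simulated counts, 26.9% of 1.5-fold changes were recovered for groups of 5 and 10.4% for Old + YM against Old.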

Other observations

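The gene families below were chosen after the results for Old against Young were seen, while the counts over other splits of the libraries were planned.

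Of 18 gene families with at least 5 tested members, 8 held more changed genes than the rest (two-sided Fisher's exact tests, adjusted over 36). These tests treat genes as independent and were run on families chosen from the same data, so camera with an estimated correlation, adjusted over the 18, stands beside each. Among proteasome subunits 17 of 38 fell (adjusted p = 6.96e-09, and adjusted p = 0.00573 with an estimated correlation), for example Psmd2 (log2 -0.45) and Psmb1 (log2 -0.48). Of 78 mitochondrial ribosomal proteins 15 fell (adjusted p = 0.00317, and adjusted p = 0.101 with an estimated correlation) and none rose, for example Mrpl12 (log2 -0.66). Of 8 class II MHC genes 6 rose (adjusted p = 3.26e-05, and adjusted p = 0.269 with an estimated correlation), for example H2-Eb1 (log2 1.49) and H2-Aa (log2 1.67), both of which are also in the macrophage list, with log2 0.90 and 0.96 without Old 5. H2-Aa had an adjusted p of 0.0516 without Young 1 and 0.0554 in a fit of these groups only, and H2-Eb1 had 0.0597 in that fit and 0.0528 with the replicate block. Of 10 chemokines 5 rose (adjusted p = 0.00258, and adjusted p = 0.118 with an estimated correlation), for example Cxcl13 (log2 2.93, and 2.15 without Old 5), which attracts B cells, and Cxcl12 (log2 1.05). Of 11 acyl-CoA synthetases 5 fell (adjusted p = 0.00423, and adjusted p = 0.0193 with an estimated correlation), for example Acsm2 (log2 -0.75). Of 14 Cyp4 genes 5 rose (adjusted p = 0.00824, and adjusted p = 0.0488 with an estimated correlation), for example Cyp4a10 (log2 1.06). Of 21 Cyp2 genes 6 fell (adjusted p = 0.0143) and 4 rose (adjusted p = 0.120), and camera gave adjusted p = 0.992 with an estimated correlation. Of 7 Akr1c genes 3 rose (adjusted p = 0.0349, and adjusted p = 0.427 with an estimated correlation) and 2 fell, for example Akr1c13 (log2 1.72) and Akr1c18 (log2 -2.63). Psmd2, Psmb1, Mrpl12, H2-Eb1, H2-Aa, Cxcl13, Cxcl12, Acsm2, Cyp4a10, Akr1c13 and Akr1c18 kept their direction and side of the threshold under the 3 other scalings. With the clock score Psmd2, Psmb1, Mrpl12, H2-Eb1, H2-Aa, Cxcl13, Cxcl12 and Acsm2 did not pass (adjusted p from 0.0625 to 0.393), as for H2-Eb1 at log2 1.70 (SE 0.62), where it was 1.49 (SE 0.38) without the score. With the clock and technical scores together Cyp4a10 did not pass either (log2 1.22, adjusted p = 0.0583).

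Other lists did not pass camera for Old against Young. These were thick ascending limb (adjusted p = 0.653), distal convoluted tubule (0.681), intercalated (0.436), endothelium (0.421), fibroblast and mural (0.0880), longevity and NAD (0.184), mitochondrially encoded (0.259), fatty acid oxidation and PPARA targets (0.653), antioxidant (0.578), autophagy and lysosome (0.233), renin-angiotensin (0.694), proliferation (0.138), blood (0.179), urothelium (0.533) and liver genes (0.190). Members still changed in several: 5 rose and 4 fell of 32 fatty acid genes (6 and 7 adjusted over the list alone), 5 rose and 4 fell of 30 antioxidant genes (5 and 8 adjusted over the list alone), and 4 rose and 1 fell of 15 fibroblast and mural genes (7 and 1 adjusted over the list alone). No fibroblast and mural gene rose without Young 1 or Old 5, 2 did without Young 2, Young 3 or Young 4, and 7 without Old + PM 3. Of fatty acid genes 2 fell without Young 1, Young 3, Young 4 or Old 5 and 1 without Young 5. Of antioxidant genes 3 rose without Young 3 or Old 5, and 7 fell without Old 4. The sign of the median differed from that of the mean or of the test for distal convoluted tubule (median log2 0.08, mean -0.08), antioxidant (-0.06 and 0.05), renin-angiotensin (0.02 and -0.01) and liver genes (median 0.27, test Down).

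Other splits of the same libraries were counted. For Old against Young, 2 of 100 drawn splits (of 126 possible), the real one included, gave as many genes as the real 1995, a share under 0.05, which argues against chance alone. The highest other split gave 2691, with Young 5 and Old 1, 2, 3 and 5 on one side, which points to a structure of the samples beside age. For Old + YM against Old, 2 of 56 splits, the real one included, gave as many as the real 3, and 52 others gave 0. That share lies under 0.05, but the highest other split gave 6, so chance is not excluded for so small a count. At an unadjusted p under 0.05, 5 of 56 splits gave as many as the real 1390, so for that count chance cannot be excluded. For Old + PM against Old the real count of edgeR was 0 (DESeq2 0, limma-voom 0) and the highest other 20, and that 56 of 56 splits gave at least 0 holds by construction and decides nothing. At an unadjusted p under 0.05, 22 of 56 splits gave as many as the real 904, the highest other gave 3069, and chance cannot be excluded for that count. For Old + PM against Old + YM the real count of edgeR was 0 (DESeq2 58, limma-voom 2) and the highest other 0, and all 10 of 10 splits reach that by construction. At an unadjusted p under 0.05 the real split gave 1878 and the highest other 914, and 10 splits are too few for a share under 0.05.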
